A study of Mus musculus with 24 samples.

How the data were processed

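Gene expression was measured in triceps surae muscle, the calf muscle group, of wild type mice and of mice lacking MuRF1, the muscle RING finger ubiquitin ligase encoded by Trim63. Per the labels the mice were 6 months old and muscle was taken 3 or 14 days after unilateral removal of a piece of the sciatic nerve, or from littermates without surgery. RNA of 24 samples was read on 1-colour Illumina mouse BeadChips, 3 samples in each of 8 groups of genotype, treatment and day. The labels do not say whether the 3 samples of a group came from separate mice, so the p-values measure the spread between these samples.

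The deposited non-normalized table holds, per the file headers, an intensity for each of 46632 probes on each array with its detection p-value; per the submitters' processing notes it was made in BeadStudio 3.2.3. From the values this intensity is on a linear scale, neither background-subtracted nor normalized between arrays. The detection p-value deposited beside each intensity lies between 0 and 1 and compares a probe with the negative control beads. The authors' processed values are intensities that were, from their distribution, background-subtracted and quantile-normalized on a linear scale without centring of genes, with medians of 13.2 to 13.4 on the 24 arrays. Higher values mean more transcript in both tables. The non-normalized table was used for the results given here and the authors' processed values, with negative values set to 0 and brought to log2 after adding 16, as an alternative.

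Probe intensities were background-corrected from the detection p-values, given an offset of 16, quantile-normalized and put on the log2 scale with the neqc function of limma 3.58.1 in R 4.3.3. A probe was kept when its detection p-value was under 0.05 on at least 3 of 24 arrays, which left 21997 probes. Gene symbols came from the array's annotation table, in which 29976 probes had 1 symbol, 10 had several and 16646 had none; 29921 were matched to current mouse genes by Entrez identifier. Of the 16314 named probes kept, the brightest per gene was used, giving 11317 genes, 3610 of which had more than 1 kept probe. Intensity on an array has no counting depth, so the number of arrays limits the precision: the median standard error of a log2 change was 0.189 between 2 groups, 0.268 for a genotype by denervation interaction and 0.134 for genotype in control muscle over both days.

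A linear model with 8 group means and 16 residual degrees of freedom was fitted to all 24 arrays with limma, with moderated statistics from its eBayes function. The 13 contrasts were denervated against control for each genotype and day, knockout against wild type in denervated muscle of each day and in control muscle over both days, the interactions of genotype, day and denervation, and day 14 against day 3 in control muscle. Tests were two-sided, and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. Where no array of a group detected a probe, a fold is given as a bound against the floor of each array, the dimmest detected signal or the probe's own signal, whichever is higher. A contrast of more than 2 groups has such a bound only where all its undetected groups pull the value the same way.

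The model, its alternatives, the naming rule and 30 gene lists were chosen before the data were examined. The genes named are, for each denervation contrast, the 8 largest rises and 8 largest falls with adjusted p under 0.05 whose 3 denervated samples all lay beyond all 3 controls. For genotype contrasts and interactions they are the 8 largest in each direction. In an interaction of genotype or of day with denervation, the denervated minus mean control values of the 2 genotypes or 2 days also had to lie apart. The interaction of all 3 factors had no such rule. Predicted gene models and clone names were passed over, any member of a gene list could be named, and Trim63 was always reported. Lists were tested against all other genes with camera of limma at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the 30 lists of a contrast. Counts within a list adjusted over the list alone equal those over all genes tested unless given.

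The lists cover ubiquitin ligases, proteasome subunits, autophagy and lysosome, acetylcholine receptor and neuromuscular synapse, myogenic and denervation-signalling regulators, p53 and growth-arrest genes, developmental, slow-fibre and fast-fibre contractile genes, and excitation-contraction coupling. Metabolic lists cover glycolysis and glycogen use, oxidative phosphorylation, the tricarboxylic acid cycle, fatty acid uptake and oxidation, polyamine metabolism, and ATF4 and amino acid stress genes. The others cover cytosolic ribosomal proteins, muscle stress and Z-disc genes, extracellular matrix, proliferation, immediate-early and handling-stress genes, the circadian clock, neighbours of Trim63, and markers of fibroblasts and adipogenic progenitors, macrophages and other leukocytes, Schwann cells and myelin, endothelium, adipocytes, tendon and cartilage, and red blood cells.

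A denervation score was computed for each sample of 1 day with the genes called in the same direction in both genotypes on the other day. It is the mean, signed by that direction, of the log2 difference between the sample and the controls of its own genotype and day. Genotypes were compared by exact permutation of the genotype labels within treatment, with 400 relabellings, two-sided, and 0.005 as the smallest p they can give. Gene order along the chromosome of Trim63 came from a mouse RefSeq table of assembly GRCm38.p6, used for which genes neighbour each other since the files name no assembly. The share of changed genes near Trim63 was compared with Fisher's exact test, two-sided. The window of 150 tested genes on each side was chosen after the gene names had been seen.

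The procedure was tested on simulated data with the same layout of arrays and 11317 genes, each gene drawn independently with its own mean and spread. Effects shared by the genes of an array were not simulated, so the values below do not cover errors from them. Of 200 genes given a change, 6 of 67 with a log2 change of 0.5, 57 of 67 with 1 and 66 of 66 with 2 were called; 9 unchanged genes were among the 138 called. A contrast with no simulated change gave no calls with limma, and none of 40 null scores had a permutation p under 0.05. Alternatives covered the values used, background correction, normalization, filters, probe choice, variance model, array weights, a replicate block, the samples in the fit, and each replicate left out in turn. Added after the data had been seen were the number of detected probes as a covariate, 2 arrays of day 3 denervated knockout muscle left out, and genes around Trim63 left out. Probes without a gene symbol were kept out of gene counts and lists.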

Results

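Transcripts were measured in the triceps surae muscle of wild type and MuRF1 knockout mice, 3 or 14 days after 1 sciatic nerve was cut, with littermates without surgery as controls. MuRF1 is a ubiquitin ligase of striated muscle, encoded by Trim63, that marks proteins for breakdown. Each of the 8 groups held 3 samples, 24 in all. Because the controls had no surgery, an effect of the operation is not separated from that of nerve loss. The median intensity per array was 124.7 to 199.8, and 15532 to 18755 of 46632 probes were detected at p under 0.05. Day 3 arrays detected 15532 to 18520 probes and day 14 arrays 16875 to 18755. Samples of a group correlated at r = 0.9741 to 0.9929 across genes, which are not independent replicates. The principal components carrying most variance held 45.2% and 19.2% of it. In 2 of the 3 day 3 denervated knockout arrays 18434 and 18520 probes were detected, against at most 17055 on the other day 3 arrays.

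Trim63 signal was at or near background in every knockout sample. In control muscle at day 3 its log2 normalized intensity was 9.44 ± 0.35 in wild type (SD, n = 3) and 4.83 to 5.14 in the 3 knockout samples, at least 12.3-fold lower (adjusted p = 1.19e-13). In denervated muscle at day 3 it was 11.03 ± 0.32 against 5.25 ± 0.10, at least 44.2-fold lower (adjusted p = 1.15e-15). At day 14 it was 23.8-fold lower in control muscle (10.29 ± 0.05 against 5.71 ± 0.05, adjusted p = 6.34e-14) and 20.9-fold lower in denervated muscle (10.07 ± 0.17 against 5.69 ± 0.19, adjusted p = 1.49e-13). In wild type muscle Trim63 rose after denervation at day 3 by 1.59 log2, and its change of -0.22 at day 14 did not pass. Trim63 had 1 probe, and its place relative to the deleted sequence is not known.

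**Figure D1:**
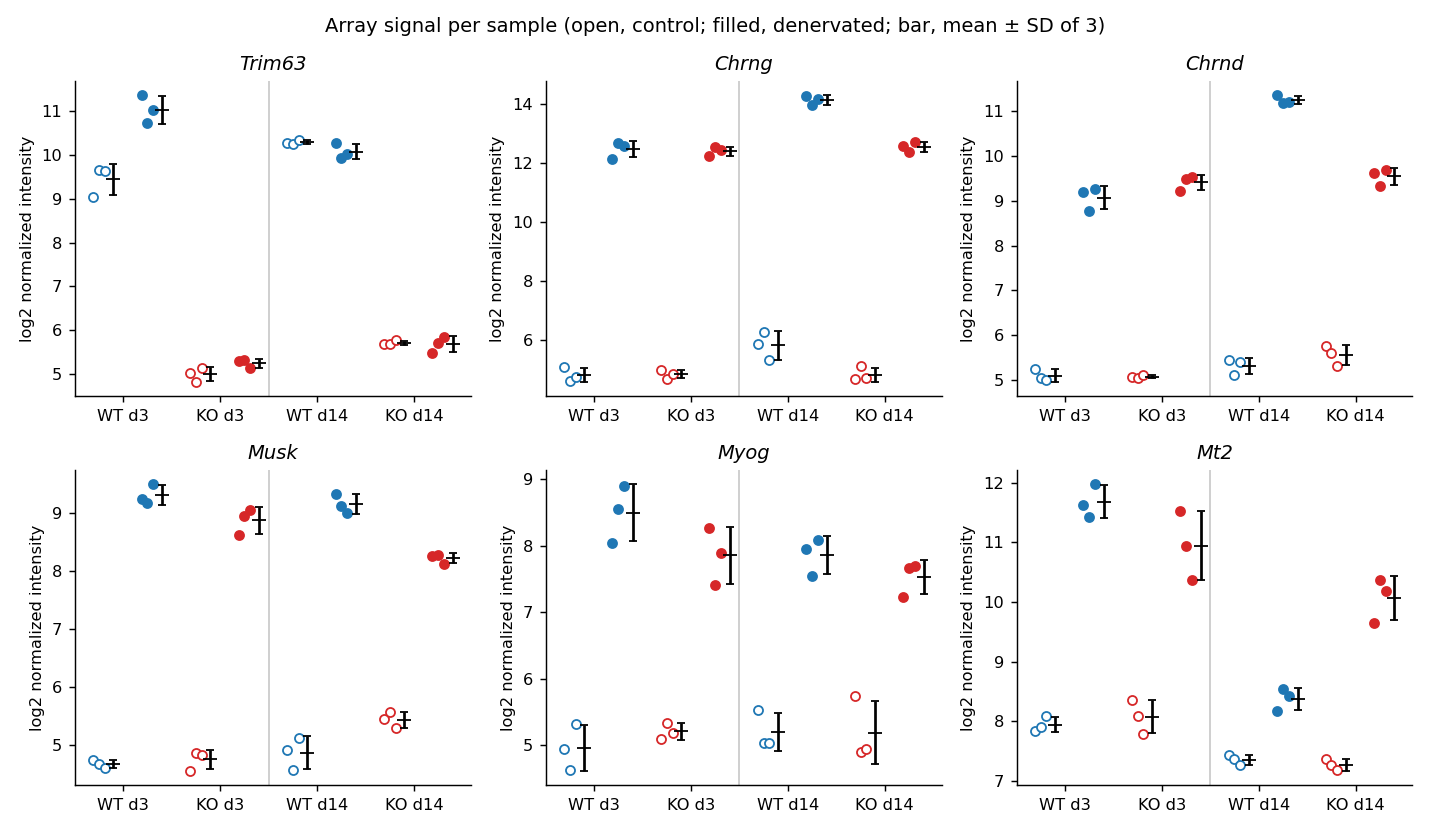
Log2 normalized intensity of 6 genes in each sample, open for control and filled for denervated muscle, with the mean and SD of 3 samples per group. Trim63 in day 3 denervated muscle averaged 11.03 in wild type and 5.25 in knockout.

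Denervation of wild type muscle for 3 days changed 4244 of 11317 genes, 2260 higher and 1984 lower, and 1398 of them at least 2-fold. The fetal acetylcholine receptor subunit Chrng went from 4.83 ± 0.23 to 12.49 ± 0.28 log2 (SD, n = 3), at least 101-fold higher. Zfp593, a gene lying near Trim63, rose 90.6-fold, and the stress-responsive ankyrin repeat gene Ankrd1 rose 69.1-fold (6.11 ± 0.16 log2, SE). Chrna9, an acetylcholine receptor subunit, rose 37.6-fold and the keratin Krt18 37.1-fold, while Orm2, Slpi and Ttyh1 rose at least 51.6-fold, 24.7-fold and 24.3-fold. The muscle genes Smco1, Perm1 and Mettl21c fell 34.7-fold, 29.2-fold and 21.9-fold, and Lrrc38, near Trim63, and Rsph1 fell 19.5-fold and 18.2-fold. Aqp4, the water channel of fast fibres, Cntnap2 and Fgfbp1 fell at least 20.1-fold, 18.9-fold and 13.1-fold. In its dimmer group Krt18 was detected on 1 of 3 arrays and Zfp593, Lrrc38 and Rsph1 on 2.

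Of the protein breakdown lists only the proteasome passed at day 3 in wild type: 28 of 31 subunits rose and 3 did not pass (median 0.92, or 0.90 with undetected genes at their bound; adjusted p = 4.57e-13), led by Psmd11 at 3.24-fold and Psmd8 at 2.84-fold. Of 18 ubiquitin ligases 5 rose and 13 did not pass (median 0.17, adjusted p = 0.0781), with Fbxo32, the atrophy ligase atrogin-1, up 2.14-fold. Autophagy and lysosome genes split 7 higher and 4 lower of 21 (median 0.11, adjusted p = 0.428). Of 16 acetylcholine receptor and synapse genes 9 rose and 3 fell (median 0.66, bound 0.37, adjusted p = 0.000323): the receptor subunit Chrnd and the synapse kinase Musk rose at least 9.49-fold and 11.1-fold, the adhesion molecule Ncam1 rose 7.42-fold, and the adult subunit Chrne fell 2.58-fold. Myogenic and denervation-signalling regulators rose in 9 and fell in 2 of 17 (10 and 2 adjusted over the list alone; median 0.54, adjusted p = 0.00168), among them Myog at least 6.39-fold and the deacetylase Hdac4 2.82-fold. Cell-cycle arrest genes Gadd45a and Cdkn1a rose 14.1-fold and 13-fold, although the p53 and growth-arrest list did not pass (6 higher and 4 lower of 12, 7 and 4 over the list alone; median 0.45, adjusted p = 0.0585).

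Energy metabolism genes fell at day 3 in wild type. Of 45 oxidative phosphorylation genes 38 fell and 7 did not pass (median -0.75, adjusted p = 9.69e-16). Of 18 tricarboxylic acid cycle genes 15 fell (16 over the list alone; median -0.85, adjusted p = 3.07e-09) with Idh2 down 8.73-fold. Of 23 fatty acid genes 19 fell and 1 rose (20 and 1 over the list alone; median -0.995, adjusted p = 2.72e-10, 0.0874 with an estimated correlation) with the lipase Lpl down 4.3-fold. Glycolysis and glycogen genes fell in 12 and rose in 2 of 20 (13 and 2 over the list alone; median -0.83, adjusted p = 2.43e-06, 0.116 with an estimated correlation), with Pfkfb3, which sets the rate of glycolysis, down 5.6-fold and Gpd1 4.48-fold. Slow-fibre genes fell in 7 and rose in 1 of 11 (8 and 1 over the list alone; median -1.02, adjusted p = 0.000454, 0.201 with an estimated correlation). Fast-fibre genes fell in 6 of 16 (median -0.30, adjusted p = 0.00177, 0.141 with an estimated correlation). Excitation-contraction coupling genes fell in 9 and rose in 1 of 16 (median -0.50, adjusted p = 0.00177, 0.0504 with an estimated correlation), where Jph2, which joins the membranes of the triad, fell 2.91-fold. Developmental contractile isoforms rose in 7 and fell in 1 of 10 (7 and 2 over the list alone; median 0.99, adjusted p = 0.00974, 0.116 with an estimated correlation).

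Genes of other cell types moved along with these at day 3 in wild type. Macrophage and other leukocyte markers rose in 17 of 19 and 2 did not pass (median 1.24, adjusted p = 1.3e-06, 0.205 with an estimated correlation), with Lgals3 up 13.1-fold. Proliferation genes rose in 16 and fell in 1 of 22 (median 1.42, bound 0.63, adjusted p = 5.88e-06, 0.0649 with an estimated correlation). Extracellular matrix genes rose in 10 and fell in 1 of 26 (median 0.40, adjusted p = 0.0224, 0.536 with an estimated correlation and 0.0767 without denervated replicate 2). Cytosolic ribosomal proteins rose in 19 of 41 (median 0.31, adjusted p = 7.21e-05, 0.241 with an estimated correlation and 0.0629 with median centring). Endothelial markers fell in 9 of 15 (median -0.50, adjusted p = 0.00244, 0.201 with an estimated correlation). Adipocyte markers fell in 6 of 12 with 1 higher (7 and 1 over the list alone; median -0.75, adjusted p = 0.0189, 0.241 with an estimated correlation and 0.0521 without control replicate 1). Tendon and cartilage markers fell in 7 of 10 with 1 higher (8 and 1 over the list alone; median -0.94, adjusted p = 0.0368, 0.401 with an estimated correlation). That call also ended with median centring (0.0674), no filter (0.0671), a stricter filter (0.0622), the covariate (0.109) and without denervated replicate 1 (0.119). Immediate-early and handling-stress genes rose in 10 of 16 (median 0.89, bound 0.68, adjusted p = 2.2e-05), with Atf3 up at least 5.08-fold, and muscle stress and Z-disc genes rose in 10 and fell in 1 of 16 (10 and 2 over the list alone; median 0.57, adjusted p = 3e-04, 0.0874 with an estimated correlation), with Ankrd2 up 5.18-fold.

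In knockout muscle at day 3 denervation changed 4052 genes, 2290 higher and 1762 lower, 1104 of them at least 2-fold, and with median centring 2144 were higher and 2747 lower. Chrng rose at least 97.5-fold and Ankrd1 108-fold (6.76 ± 0.16 log2, SE), Rrad, a small GTPase, rose 39-fold, Chrna9 34.1-fold and the neutrophil protein S100a8 30.2-fold. Ttyh1, Runx1 and Zfp593 rose at least 23.7-fold, 23.1-fold and 24.3-fold. Smco1 fell 30.3-fold, Perm1 24-fold, Rsph1 24-fold, Emid1 20-fold, Mettl21c 14.5-fold, Aqp4 11.4-fold and Map2k6 11.1-fold, and Cntnap2 fell at least 14-fold. Map2k6 was detected on 1 of 3 arrays of its dimmer group, and Rrad, S100a8 and Emid1 on 2. Without control replicates 1 and 3 in turn S100a8 rose 46-fold and 18.6-fold. With the 2 arrays of most detected probes left out, 1932 genes were called.

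By list, 25 of 31 proteasome subunits rose in day 3 knockout muscle and 6 did not pass (median 0.73, adjusted p = 3.67e-09), with Psmd11 up 3.26-fold, and 11 of 16 synapse genes rose and 3 fell (median 0.65, adjusted p = 0.00012), with Chrnd up at least 12.1-fold. Myogenic regulators rose in 9 and fell in 3 of 17 (10 and 3 over the list alone; median 0.99, adjusted p = 0.000714). Muscle stress genes rose in 12 and fell in 1 of 16 (12 and 2 over the list alone; median 0.90, adjusted p = 6.49e-06). Immediate-early genes rose in 10 of 16 (median 1.04, adjusted p = 6.85e-05). Oxidative phosphorylation genes fell in 38 of 45 (39 over the list alone; median -0.78, adjusted p = 3.9e-20). Tricarboxylic acid cycle genes fell in 13 of 18 (median -0.65, adjusted p = 1.74e-06). Coupling genes fell in 7 of 16 with 1 higher (8 and 1 over the list alone; median -0.39, adjusted p = 0.00299). Fatty acid genes fell in 13 and rose in 1 of 23 (14 and 1 over the list alone; median -0.71, adjusted p = 1.36e-06, 0.201 with an estimated correlation), and Idh2 fell 4.34-fold. Glycolysis genes fell in 7 and rose in 3 of 20 (8 and 3 over the list alone; median -0.14, adjusted p = 0.0267, 0.504 with an estimated correlation), a call lost without control knockout replicate 3 (adjusted p = 0.0995) and without denervated knockout replicate 1 (0.207). Macrophage markers rose in 4 of 19 (median 0.54, adjusted p = 0.018, 0.561 with an estimated correlation), lost without the same samples (0.173 and 0.342). Autophagy genes rose in 11 and fell in 1 of 21 (12 and 2 over the list alone; median 0.35, adjusted p = 0.00572), with adjusted p = 0.201 with an estimated correlation, 0.254 with the covariate and 0.131 without the 2 arrays of most detected probes.

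At day 14 denervation of wild type muscle changed 4698 genes, 2594 higher and 2104 lower, 1527 at least 2-fold. Chrng rose 318-fold (8.31 ± 0.20 log2, SE), the sarcomere protein Igfn1 121-fold, the keratin Krt18 113-fold and its partner Krt8 at least 139-fold. S100a8 rose 64.8-fold, Runx1 41.9-fold, Rrad 35.6-fold and Chrnd at least 48.9-fold. Dhrs7c, a sarcoplasmic reticulum enzyme, fell 37.2-fold, Aqp4 31.4-fold, Smco1 31.1-fold, Mlf1 22.9-fold, Lrrc38 21.2-fold, Emid1 19-fold and Ramp1 15.8-fold. Cntnap2 fell at least 17.8-fold. Detection in the dimmer group was on 1 of 3 arrays for Krt18 and Emid1 and on 2 for Chrng, S100a8, Runx1 and Aqp4. The perinatal myosin Myh8 rose 30.4-fold (4.92 ± 0.31, SE) and the embryonic troponin Tnnt2 17.3-fold, while Fbp2, an enzyme of glycogen synthesis from lactate, fell 12.2-fold. Fbxo32 stood at 0.04 log2 and did not pass (adjusted p = 0.932).

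Synapse genes rose in 8 and fell in 1 of 16 at day 14 in wild type (median 0.51, bound 0.40, adjusted p = 0.000136). Myogenic regulators rose in 10 and fell in 3 of 17 (median 0.84, adjusted p = 0.00411) with Hdac4 up 8.86-fold. P53 and growth-arrest genes rose in 7 and fell in 2 of 12 (median 0.92, adjusted p = 0.00386, 0.165 with an estimated correlation) with Cdkn1a up 22.3-fold. Proteasome subunits rose in 17 and fell in 1 of 31 (19 and 1 over the list alone; median 0.49, adjusted p = 0.000214, 0.165 with an estimated correlation), the subunit that fell being Psmd2, by 2.56-fold. Ubiquitin ligases rose in 10 and fell in 1 of 18 (median 0.52, adjusted p = 0.0391, 0.349 with an estimated correlation), with Mdm2 up 2.59-fold, a call that also ended with the mean of probes (0.173), a stricter filter (0.0594) and the covariate (0.0894). Oxidative phosphorylation genes fell in 36 and rose in 1 of 45 (37 and 1 over the list alone; median -0.77, adjusted p = 4.97e-14). Tricarboxylic acid cycle genes fell in 14 of 18 (16 over the list alone; median -0.91, adjusted p = 2.61e-09). Coupling genes fell in 9 of 16 with 1 higher (9 and 2 over the list alone; median -0.70, adjusted p = 0.000476). Glycolysis genes fell in 14 of 20 with 1 higher (median -0.83, adjusted p = 9.9e-07, 0.139 with an estimated correlation). Fatty acid genes fell in 18 of 23 (median -0.95, adjusted p = 3.05e-08, 0.153 with an estimated correlation). Developmental isoforms rose in 6 and fell in 3 of 10 (median 1.20, adjusted p = 0.0209, 0.165 with an estimated correlation and 0.0523 with only the day's samples in the fit). Endothelial markers fell in 10 of 15 (11 over the list alone; median -0.85, adjusted p = 9.66e-05, 0.139 with an estimated correlation). Fibroblast markers fell in 7 of 12 (median -0.61, adjusted p = 0.00278, 0.207 with an estimated correlation). Macrophage markers did not pass (5 of 19 higher, 3 over the list alone; median 0.18, adjusted p = 0.484).

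In knockout muscle at day 14 denervation changed 4154 genes, 2149 higher and 2005 lower, 1228 at least 2-fold. Chrng rose at least 124-fold, S100a8 125-fold, Igfn1 53.6-fold, Rrad 43.8-fold and Ankrd1 42.9-fold, and Krt18, Krt8 and Runx1 rose at least 55.5-fold, 40.9-fold and 24.5-fold. Dhrs7c fell 38.5-fold, Perm1 28.6-fold, Smco1 26.1-fold, the muscle protease Ky 21-fold, Lrrc38 19-fold and Emid1 13.1-fold, and Aqp4 and Cntnap2 fell at least 21.9-fold and 13.5-fold. S100a8, Lrrc38 and Emid1 were detected on 2 of 3 arrays of their dimmer group. Fbxo32 rose 2.43-fold (adjusted p = 0.00106), and the metal-binding proteins Mt1 and Mt2 rose 7.35-fold and 6.98-fold.

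The proteasome rose in 24 and fell in 1 of 31 at day 14 in the knockout (median 0.63, adjusted p = 2.72e-08, 0.053 with an estimated correlation), with Psmc1 up 7.47-fold. Synapse genes rose in 7 and fell in 2 of 16 (median 0.08, adjusted p = 0.00521), with Chrnd up 15.7-fold. Myogenic regulators rose in 10 and fell in 3 of 17 (11 and 3 over the list alone; median 1.01, adjusted p = 0.000265). Developmental isoforms rose in 6 and fell in 1 of 10 (6 and 2 over the list alone; median 1.62, adjusted p = 0.000654, 0.053 with an estimated correlation) with Myh8 up 11.2-fold. Tricarboxylic acid cycle genes fell in 17 of 18 and 1 did not pass (18 over the list alone; median -1.03, adjusted p = 2.71e-12). Oxidative phosphorylation genes fell in 31 of 45 (32 over the list alone; median -0.59, adjusted p = 6.72e-12, 0.053 with an estimated correlation). Glycolysis genes fell in 15 of 20 (16 over the list alone; median -0.90, adjusted p = 1.13e-09, 0.053 with an estimated correlation). Fatty acid genes fell in 16 of 23 (18 over the list alone; median -0.76, adjusted p = 2.5e-08, 0.155 with an estimated correlation). Ribosomal protein genes rose in 28 of 41 (median 0.50, adjusted p = 1.62e-07, 0.182 with an estimated correlation), with Rpl38 up 2.19-fold. Macrophage markers rose in 14 of 19 (16 over the list alone; median 1.19, adjusted p = 5.36e-05, 0.345 with an estimated correlation), with Ccl8 up 11.1-fold. Immediate-early genes rose in 10 of 16 (12 over the list alone; median 1.03, adjusted p = 4.12e-07).

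**Figure D2:**
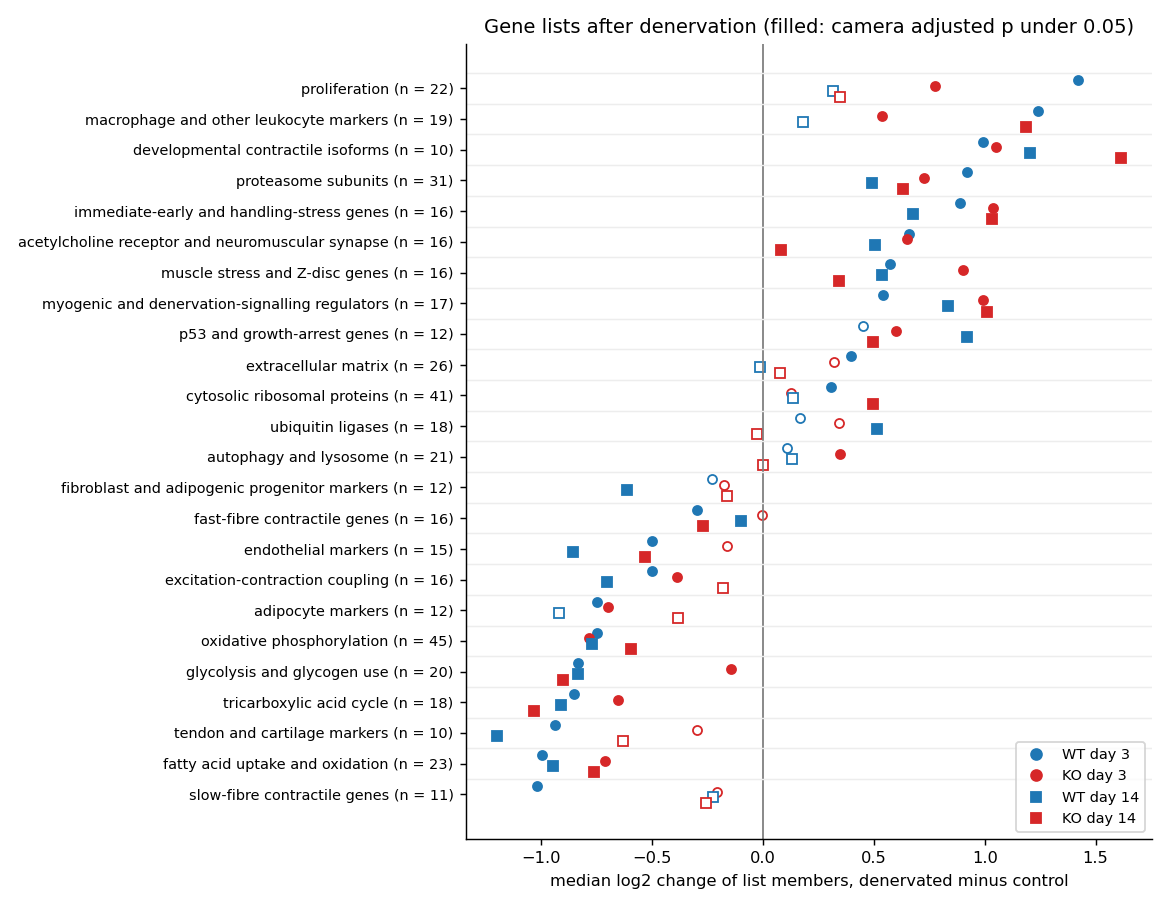
Median log2 change after denervation of 24 gene lists in the 4 combinations of genotype and day, filled where the list differed from other genes at adjusted p under 0.05 by camera. The proteasome list lies between 0.49 and 0.92 and the oxidative phosphorylation list between -0.78 and -0.59.

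Both genotypes shared most of the response. At day 3, 2644 genes changed the same way in both, 1475 higher and 1169 lower against 457 and 309 for independent lists, and 10 changed in opposite ways against 753. At day 14 the numbers were 2512 shared, 1341 higher and 1171 lower against 493 and 373, and 80 opposite against 859. In all 4 comparisons 764 genes rose and 659 fell. Across the 390 list tests 133 passed with the preset correlation and 26 with an estimated correlation. Those 26 were synapse genes, myogenic regulators and the tricarboxylic acid cycle in all 4 denervation comparisons. Oxidative phosphorylation held in all but day 14 knockout, and the proteasome on day 3 in both genotypes. Immediate-early genes held in all but day 14 wild type, coupling genes in all but day 3 wild type and day 14 knockout, and muscle stress genes in day 3 knockout. The others were the synapse list in the day 14 interaction and in the day 14 genotype comparison, and the Trim63 neighbours in day 3 denervated muscle.

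Acetylcholine receptor and synapse genes were lower in denervated knockout than in denervated wild type muscle at day 14. Of 16, 10 were lower and 6 did not pass (median -0.63, adjusted p = 2e-08, and 0.000182 with an estimated correlation). Chrnd was 3.25-fold lower (9.54 ± 0.20 against 11.24 ± 0.09 log2, SD, n = 3; adjusted p = 5.17e-07) and Chrng 2.98-fold lower (12.57 ± 0.17 against 14.15 ± 0.16, adjusted p = 5.93e-05). Ncam1, Musk, Chrna1, Chrne and the agrin receptor Lrp4 were lower by 1.91-fold, 1.90-fold, 1.75-fold, 1.73-fold and 1.68-fold. The interaction of genotype and denervation at day 14 gave the list a median of -0.52, with 4 lower (5 over the list alone; adjusted p = 0.00161, and 0.0287 with an estimated correlation), including Chrnd, lower by at least 1.63 log2 (adjusted p = 6.88e-05), and Musk (adjusted p = 0.000412). Musk was at background in control muscle of both genotypes, so its interaction has no bound.

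In all, knockout and wild type denervated muscle at day 14 differed in 789 genes, 311 higher and 478 lower, 131 at least 2-fold, and with median centring in 261 higher and 731 lower. Hyi, 150 tested genes from Trim63, was 9.17-fold higher and Wdfy1 7.38-fold. Tsc22d3, a glucocorticoid-induced gene, Mt2, Cyp4f14, Ccdc110, Il12a and Hp were 3.33-fold, 3.24-fold, 3.59-fold, 3.48-fold, 3.29-fold and 3.2-fold higher. Pnrc2, Necap2, Eya3 and Zmym6, which lie near Trim63, were 20.7-fold, 6.64-fold, 6.39-fold and 4.49-fold lower. Kcnq5, the actin-binding Xirp2 and the adhesion gene Nrcam were 11.1-fold, 6.85-fold and 5.13-fold lower. In control muscle a second probe of Xirp2 stood at 0.05 log2 against -1.71 for the probe used. Kcnq5 was detected on 1 of 3 knockout arrays (6.42 ± 2.02 against 9.89 ± 0.14 log2, SD, n = 3; adjusted p = 0.00422). It was 25-fold lower without denervated knockout replicate 3 and 7.07-fold without replicate 2. Wild type muscle had Cyp4f14 on 1 of 3 arrays and Ccdc110 on 2. Fbxo32 was 2.11-fold higher (adjusted p = 0.0251) and Mt1 2.73-fold higher. Macrophage markers were higher as a list, with 1 gene lower by itself (5 higher and 1 lower over the list alone; median 0.68, adjusted p = 0.000167, 0.447 with an estimated correlation). The call of Hp ended in 10 of 18 alternatives, with each of the 6 samples left out in turn among them, and that of Xirp2 with the mean of probes (adjusted p = 0.0664). Endothelial markers were higher in 2 of 15 (5 over the list alone; median 0.32, adjusted p = 0.000211, 0.447 with an estimated correlation). In all 9 lists passed with the preset correlation, and only the synapse list with an estimated one. Besides those given here and the circadian list, they were the slow-fibre, adipocyte, extracellular matrix, fibroblast and ribosomal protein lists. Their calls ended in 14, 6, 2, 2 and 1 of 19 alternatives in turn. The number of genes called was 301 without denervated knockout replicate 2, 359 without replicate 3, and 439, 413 and 342 without denervated wild type replicates 1, 2 and 3.

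The day 14 interaction passed in 1416 genes, 519 with a higher and 897 with a lower change in the knockout, 457 of them at least 2-fold, and with median centring in 451 and 1331. It also holds the genotype difference of the controls, so it is not a measure of denervated muscle alone. Genotype by itself passed in 621 genes in day 14 control muscle, against 58 in day 3 control muscle and 789 in day 14 denervated muscle. Gsn, the actin-severing gelsolin, had an interaction of 2.30 ± 0.53 log2 (SE, adjusted p = 0.00835) and Mt1 of 2.01 ± 0.24 (adjusted p = 8.52e-05). Others were Atg4d at 2.26, Hyi at 2.13, Psmd2, Btbd2 and Tsc22d3 at 2.12 and Rnf126 at 2.10. By genotype in control muscle a second probe of Atg4d went the other way, at 0.57 log2 against -0.61 for the probe used. That of Hyi stood at 0.28 against 1.75. Lower were Ttc39c at -2.36, Scaper at -2.09, Gatad2a at -2.05, the cytoskeletal Map1b at -2.00 ± 0.22 (adjusted p = 6.88e-05), and the fast myosin Myh1 at -1.98. Nrcam (adjusted p = 0.000675) and Mycl and Ncmap, near Trim63 (0.00166 and 0.000118), also passed as lower, with 2 or 3 of their 4 groups at background, so the interaction has no bound. Ttc39c was detected on 1 of 3 wild type control arrays, Btbd2 on 2 of 3 in 2 groups and Scaper on 2 of 3 denervated knockout arrays. Without control wild type replicate 2 Hyi stood at 1.51 and Gatad2a at -1.41, and without denervated wild type replicate 1 Ttc39c stood at -3.08. Fbxo32 was at 1.24 ± 0.40 (adjusted p = 0.0441). Ribosomal proteins (median 0.32, 4 of 41 higher, adjusted p = 6.36e-05, 0.572 with an estimated correlation), macrophage markers (median 0.91, 2 of 19 higher, 4 over the list alone, adjusted p = 0.000169, 0.732 with an estimated correlation), coupling genes (median 0.50, 5 of 16 higher, adjusted p = 0.004, 0.141 with an estimated correlation) and fibroblast markers (median 0.49, 2 of 12 higher, adjusted p = 0.00774, 0.572 with an estimated correlation) had a higher change in the knockout. The call of Atg4d ended with the mean of probes (adjusted p = 0.0545) and that of Gatad2a without control knockout replicate 1 (adjusted p = 0.0532) and with only the day's samples (0.0536). The number passing was 884 without control knockout replicate 2, 803 without control wild type replicate 2, 708 without denervated knockout replicate 2 and 907 without denervated wild type replicate 2.

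In denervated muscle at day 3 knockout and wild type differed in 812 genes, 430 higher and 382 lower, 110 at least 2-fold, and with median centring in 324 higher and 646 lower. Proteasome subunits were lower in 11 of 31 and 20 did not pass (15 over the list alone; median -0.38, adjusted p = 2.32e-09, 0.104 with an estimated correlation), with Psmd14 at -0.84 log2 and Psma7 at -0.72. Glycolysis genes were higher in 9 of 20 (12 over the list alone; median 0.57, adjusted p = 2.18e-07, 0.266 with an estimated correlation), among them the glycogen enzyme Phkg1 by 2.45-fold, Pfkfb3 by 2.20-fold and Gpd1 by 2.08-fold. Cops8 was 6.63-fold higher, Wdfy1 5.57-fold, Hyi 4.45-fold, the sialidase Neu2 3.55-fold and Ddit4l 3.37-fold, with B3galt6 at 3.36-fold and Ccdc110 and Fgfbp1 at least 2.79-fold and 2.52-fold higher. Pnrc2, Necap2 and Cd52, near Trim63, were 19-fold, 8.2-fold and 6.85-fold lower. Xirp2 was 6.39-fold, Kcnq5 5.84-fold and Orm2 5.83-fold lower, and Zbtb8os, near Trim63, at least 4.8-fold. Detection in the dimmer group was on 1 of 3 arrays for Cd52 and on 2 for B3galt6 and Kcnq5. Cops8 was 11.7-fold higher without denervated wild type replicate 3, and B3galt6 2.12-fold without replicate 2. The calls of B3galt6 and Kcnq5 ended in 12 and 8 of 19 alternatives. Those of Cops8, Fgfbp1 and Ddit4l ended in 2 of 19, of Ccdc110 in 2 of 18 and of Cd52 in 2 of 17, with no single left-out sample among them. Those of Cops8, Ccdc110, Fgfbp1, Ddit4l, Cd52 and Xirp2 ended without the 2 arrays of most detected probes (adjusted p = 0.0521 to 0.23). The Trim63 neighbours were lower in 8 and higher in 3 of 30 (10 and 3 over the list alone; median -0.17, adjusted p = 0.000963). Fast-fibre genes were higher in 4 of 16 (7 over the list alone; median 0.29, adjusted p = 0.00148, 0.335 with an estimated correlation and 0.448 with median centring). Endothelial markers were higher in 1 of 15 (median 0.25, adjusted p = 0.0171, 0.628 with an estimated correlation and 0.0824 without denervated knockout replicate 1). Ribosomal proteins were lower in 1 of 41 (4 over the list alone; median -0.19, adjusted p = 2.87e-05, 0.567 with an estimated correlation) and oxidative phosphorylation genes in 2 of 45 (median -0.11, adjusted p = 0.00927, 0.776 with an estimated correlation). Proliferation genes were lower in 2 of 22 (3 over the list alone; median -0.41, adjusted p = 0.00927), a call that ended with an estimated correlation (0.567), with a stricter filter (0.221) and without denervated wild type replicate 3 (0.0674). Macrophage markers were lower in 1 of 19, which was Cd52, also a neighbour of Trim63 (median -0.30, adjusted p = 0.0192). That list call ended with an estimated correlation (0.835), median centring (0.0946), a stricter filter (0.105) and genes around Trim63 left out (0.115). It also ended without denervated wild type replicates 2 and 3 (0.152 and 0.0515) and without denervated knockout replicate 3 (0.874, median 0.08). With the covariate the calls of the fast-fibre, ribosomal, oxidative phosphorylation, proliferation and macrophage lists ended (0.0923, 0.303, 0.946, 0.48 and 0.197), and without the 2 arrays too (0.0554, 0.228, 0.745, 0.297 and 0.242). There the macrophage median turned to 0.40 and 0.34. The count was 24 with the 2 arrays of most detected probes left out, 2171, 179 and 196 without denervated knockout replicates 1, 2 and 3, and 343 and 213 without denervated wild type replicates 2 and 3.

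The day 3 interaction passed in 124 genes, 74 higher and 50 lower. Cops8 stood at 2.85 log2 (adjusted p = 0.0254), Ddit4l at 2.34 (adjusted p = 0.00635), Pfkfb3 at 2.30 (adjusted p = 0.0207) and Neu2 at 2.04 (adjusted p = 0.000457). With 1 group at background, Fgfbp1 stood at least at 2.32 (adjusted p = 0.000457), Ccdc110 at 1.74, Fam83d at 1.56 and the aminotransferase Abat at 1.41. Lower were Rbp7, near Trim63, at -3.48, Dupd1 at -2.22 and Sec61b at -2.12. Orm2, Gsta1, Gsta2, Sidt1 and Zbtb8os, the last near Trim63, also passed as lower (adjusted p = 0.00337, 0.00676, 0.0125, 0.0332 and 0.000457), with 2 or 3 of their 4 groups at background, so the interaction has no bound. Rbp7 was detected on 2 of 3 wild type control arrays, and it stood at -4.27 and -2.71 without replicates 1 and 2 of that group. Cops8 stood at 3.68 without denervated wild type replicate 3. Fam83d and Ccdc110 had 1 or 2 of 3 arrays detected in 2 groups each, and Zbtb8os 1 of 3 in wild type control muscle. Glycolysis genes had a higher change in the knockout, 3 of 20 genes (10 over the list alone; median 0.60, adjusted p = 1.81e-07, 0.358 with an estimated correlation), with Phkg1 at 1.45 ± 0.26 (SE, adjusted p = 0.00986) and Gpd1 at 1.16 ± 0.20 (adjusted p = 0.0071). Macrophage markers had a lower change (median -0.74, 2 of 19 over the list alone, adjusted p = 1.06e-05, 0.364 with an estimated correlation, 0.129 with the covariate and 0.164 without the 2 arrays of most detected probes). With those 2 arrays left out 3 genes passed. The calls of Rbp7 and Sidt1 ended in 14 and 9 of 24 alternatives, and those of Cops8, Fam83d and Pfkfb3 in 10, 10 and 7 of 25. Single left-out samples made up 8, 6, 7, 8 and 4 of these in turn. Without the 2 arrays the calls of Ccdc110, Ddit4l, Orm2, Gsta1, Gsta2, Dupd1, Sec61b and Abat ended too (adjusted p = 0.0795 to 0.302), and with the covariate all of these but Abat (0.0545 to 0.178). Those of Ccdc110 and Orm2 also ended with only the day's samples (0.0754 and 0.0526) and that of Gsta2 with the authors' values (0.0929). The count was 43, 38 and 53 without control wild type replicates 1, 2 and 3. It was 33, 56 and 622 without control knockout replicates 1, 2 and 3. It was 81, 44 and 37 without denervated wild type replicates 1, 2 and 3, and it was 985, 36 and 31 without denervated knockout replicates 1, 2 and 3.

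Without denervation, knockout and wild type muscle differed in 374 genes over both days, 178 higher and 196 lower, 30 at least 2-fold, with the mean of probes in 99 higher and 185 lower. Pnrc2 was 26.8-fold lower, the deiminase Padi2 6.03-fold, the small heat shock protein Hspb7 5.45-fold, Eya3 4.65-fold and Necap2 3.61-fold, all near Trim63, and Kcnq5 and Rab6b, which lie elsewhere, at least 4.91-fold and 3.13-fold. Rbp7, Hyi and the zinc transporter Slc30a2, near Trim63, were 4.45-fold, 3.36-fold and 2.58-fold higher, and Ncmap there at least 2.22-fold. Wdfy1, Itgb3bp and Tbc1d1 were 3.05-fold, 2.17-fold and 2.15-fold higher, and Cep170 at least 1.71-fold. A second kept probe showed little or no change for Rbp7, Hyi and Eya3, at -0.17, 0.28 and -0.02 log2 against 2.15, 1.75 and -2.22. For Wdfy1 and Tbc1d1 it had the same sign, at 0.45 and 0.83 against 1.61 and 1.10. Second probes were compared in control muscle only, also for genes named in denervated muscle. Padi2 was detected on 1 of 3 knockout arrays of each day, and Kcnq5 on 1 of 3 at day 3. Pnrc2 and Eya3 were detected on 2 of 3 day 3 knockout arrays, Rab6b in 2 groups on 2 of 3, and Rbp7, Slc30a2 and Cep170 in 1 wild type group on 2 of 3. The call of Rab6b ended in 16 of 23 alternatives. Of the planned list of Trim63 neighbours 9 of 30 differed, against 364 of 11286 other genes, an odds ratio of 12.8 (95% interval 5.14 to 29.5, two-sided Fisher's exact p = 3.23e-07). In a window set after the gene names had been seen, the 150 tested genes on each side of Trim63, 46 of 300 (15.3%) differed, against 327 of 11000 others (2.97%), an odds ratio of 5.91 (95% interval 4.14 to 8.29, two-sided Fisher's exact p = 1.13e-18), and at most 12 did in 28 windows of 300 genes elsewhere. Of 29 genes other than Trim63 that differed at least 2-fold, 18 lay in the window, 2 elsewhere on that chromosome and 9 on others. Slow-fibre genes were lower as a list (8 of 11 over the list alone; median -0.33, adjusted p = 0.000442), fatty acid genes were lower in 4 of 23 (5 over the list alone; median -0.22, adjusted p = 0.000358, 0.486 with an estimated correlation), and no list passed with an estimated correlation. The count was 201 and 738 without day 3 control knockout replicates 1 and 3, 207 and 232 without day 3 control wild type replicates 2 and 3. It was 226 and 169 without day 14 control knockout replicates 1 and 3, and 186 without day 14 control wild type replicate 2.

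**Figure D3:**
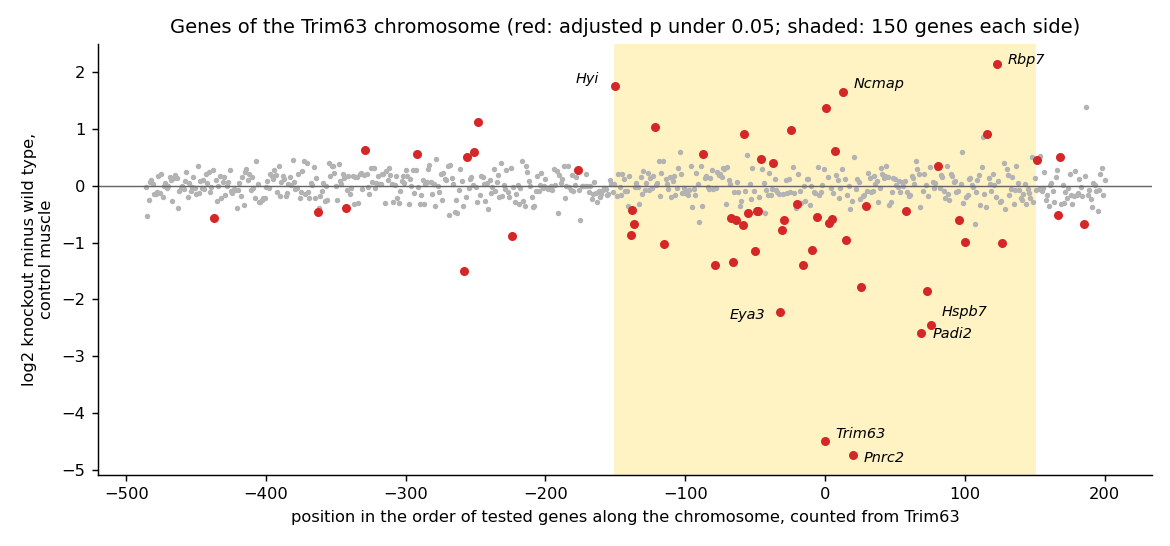
Log2 difference of knockout minus wild type in control muscle for each tested gene on the chromosome of Trim63, by gene order from Trim63, with the window of 150 genes on each side shaded. In the window 46 of 300 genes passed.

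The denervation score asked whether the shared response was of equal size in both genotypes. With the 2644 genes shared at day 3, day 14 denervated muscle scored 0.9394 ± 0.0343 in wild type and 0.793 ± 0.0371 in knockout (SD, n = 3), a difference of -0.1464 (exact permutation p = 0.005, the smallest that 400 relabellings give). In 2 alternatives only the choice of day 3 genes changed, while the day 14 samples and their values stayed the same. With genes chosen under the number of detected probes as a covariate the difference was 0.0402, with its sign reversed (exact permutation p = 0.055). With genes chosen without the 2 day 3 arrays of most detected probes it was -0.0348 (exact permutation p = 0.125). Day 14 scores adjusted for detected probes were not tested. With the 2512 genes shared at day 14, day 3 muscle scored 0.9352 ± 0.0179 and 0.7463 ± 0.03, a difference of -0.1889 (exact permutation p = 0.015). With all 4244 and 4698 genes called in wild type neither difference passed, at -0.026 (exact permutation p = 0.2) and -0.0608 (exact permutation p = 0.185). With all genes called in knockout the differences were -0.1895 (exact permutation p = 0.005) and -0.2302 (exact permutation p = 0.015). With genes changed at least 2-fold in both they were -0.1195 (exact permutation p = 0.01) and -0.2838 (exact permutation p = 0.02).

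**Figure D4:**
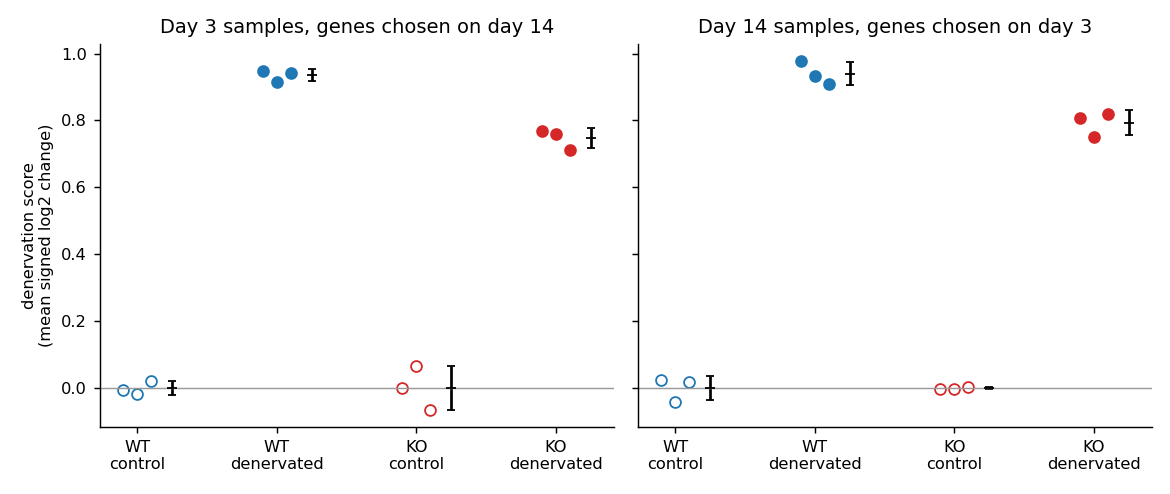
Denervation score of each sample, the mean signed log2 change of genes shared by both genotypes on the other day, for control and denervated muscle. At day 14 denervated wild type averaged 0.9394 and knockout 0.793.

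The response differed between days in 1549 genes in wild type, 845 higher and 704 lower at day 14, and in 2330 in knockout, 1030 higher and 1300 lower. In wild type Myh8 stood at 3.59 log2, Igfn1 at 3.30, Fam83d at 3.29 and Aldh3a1 at 3.07. The histone gene H2ac12 stood at -3.35, Zfp593, near Trim63, at -3.04 and Angptl4 at -3.03, and the cell division motor Kif23, at background in day 3 control muscle, was lower by at least 2.63. Bpifb1 passed as higher (adjusted p = 5.29e-10) with 3 of its 4 groups at background and no bound. Fam83d and Zfp593 had 1 or 2 of 3 arrays detected in 2 groups each. Macrophage markers (8 of 19 lower, median -1.12, adjusted p = 2.26e-06, 0.545 with an estimated correlation), proliferation genes (9 of 22 lower, median -0.50, adjusted p = 0.000214, 0.392 with an estimated correlation and 0.0653 with a stricter filter) and the proteasome (9 of 31 lower, 12 over the list alone, median -0.44, adjusted p = 8.52e-06, 0.392 with an estimated correlation) had a smaller change at day 14, and slow-fibre genes a higher one (5 of 11, median 0.76, adjusted p = 8.54e-06, 0.392 with an estimated correlation). In knockout Ear3 stood at 3.76, Mt3 at 3.47 and Uchl1 at 3.45, while Chrna9 stood at -2.65 and Ddit4l at -2.65, and Txnl1, at background in day 3 control muscle, was lower by at least 2.36. Mt3 had 1 or 2 of 3 arrays detected in 2 groups, Uchl1 and Txnl1 2 of 3 in 1 group. Ear3 stood at 4.41 without day 3 control knockout replicate 3 and at 4.43 without denervated knockout replicate 1, where the fitted value of Txnl1 moved from -3.18 to -3.99. The call of Txnl1 ended without day 3 denervated knockout replicate 2 (adjusted p = 0.0549) and with the covariate (0.0885). Without the 2 arrays of most detected probes those of Txnl1 and Ear3 ended (0.4 and 0.0789). With all arrays in the fit, glycolysis genes of the knockout had a lower change at day 14 (12 of 20, 15 over the list alone, median -0.70, adjusted p = 5.06e-07, 0.619 with an estimated correlation) and ribosomal proteins a higher one (16 of 41, 24 with 1 lower over the list alone, median 0.42, adjusted p = 1.23e-05, 0.619 with an estimated correlation). The knockout count was 1480 without day 14 denervated knockout replicate 2, 1532 and 1425 without day 3 denervated knockout replicates 2 and 3, and 220 without the 2 arrays of most detected probes.

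Genotype, day and denervation interacted in 1645 genes, 669 higher and 976 lower. The chemokine Ccl12 stood at least at 3.65 log2 and Ccl7 at 3.39, Sec61b at 3.87, H2ac12 at 3.70 and Angptl7, near Trim63, at 3.52. Myh1 stood at -3.59, Ddit4l at -2.91 and the M-band gene Myom3, near Trim63, at -2.78, and Fam83d and Abat were lower by at least 2.96 and 2.41. Each of the 3 genes with a bound had 1 group at background, and Ccl12 and Fam83d had 1 or 2 of 3 arrays detected in 2 and 3 other groups. Without day 3 control knockout replicates 2 and 3 H2ac12 stood at 3.03 and 4.44 and Ccl7 at 2.77 and 4.001. Without day 3 denervated knockout replicate 3 Ccl7 stood at 2.80 and the fitted value of Ccl12 moved from 4.16 to 3.54, and without day 14 control knockout replicate 3 Angptl7 stood at 4.11. Without the 2 arrays of most detected probes the calls of Ccl12, Ccl7, H2ac12, Angptl7, Fam83d, Myh1 and Ddit4l ended (adjusted p = 0.0515 to 0.149). Macrophage markers were higher in 7 of 19 (12 over the list alone; median 1.71, adjusted p = 3.36e-07, 0.481 with an estimated correlation). Ribosomal proteins were higher in 11 of 41 (21 with 2 lower over the list alone; median 0.55, adjusted p = 1.2e-07, 0.481 with an estimated correlation). Glycolysis genes were lower in 7 of 20 (9 over the list alone; median -0.65, adjusted p = 0.000403, 0.481 with an estimated correlation). The count was 1028 without day 14 denervated knockout replicate 2, 2699, 1004 and 1067 without day 3 denervated knockout replicates 1, 2 and 3, and 99 without the 2 arrays of most detected probes.

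Control muscle differed between the days in 4685 genes, 2656 higher and 2029 lower at day 14, 216 of them at least 2-fold, and in 224 with the number of detected probes as a covariate. The labels give no batch, so the day cannot be separated from differences between arrays handled at different times. The clock gene Arntl rose by 1.66 log2 and Pdk4, which spares glucose, by 1.63, and Gadd45b and the muscle transcription factor Mef2c changed by -2.01 and -1.40. Ribosomal proteins were lower in 21 of 41 (22 over the list alone; median -0.22, adjusted p = 6.6e-06, 0.654 with an estimated correlation and 0.257 with median centring). Macrophage markers were lower in 12 of 19 (13 over the list alone; median -0.74, adjusted p = 0.000113, 0.654 with an estimated correlation and 0.66 with the covariate). Glycolysis genes were higher in 10 of 20 (12 over the list alone; median 0.30, adjusted p = 0.0399, 0.654 with an estimated correlation and 0.866 with the covariate). That call also ended with a stricter filter (0.0594) and without day 3 control knockout replicate 1 (0.06) and day 14 control wild type replicate 1 (0.0582).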

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

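All tests of explanations given here, and the counts over other divisions of the samples, were chosen after the results they concern had been seen. The interactions, scores and list tests themselves were planned.

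Differences of the response to denervation between genotypes or days were tested by interaction terms or permutation, and these values passed. For none of the interactions could the other divisions of the arrays decide whether chance gave the counts. Genotype and denervation interacted in 124 genes at day 3 and in 1416 at day 14, day and denervation in 1549 genes in wild type and 2330 in knockout, and all 3 factors in 1645. The denervation score differed between genotypes by -0.1464 at day 14 and by -0.1889 at day 3. The day 14 difference turned to 0.0402 with day 3 genes chosen under the detected-probe covariate (permutation p = 0.055), the scores themselves being unadjusted. With genes called in wild type neither passed (permutation p = 0.2 and 0.185). The median of the synapse list in the day 14 interaction was -0.5183. Probes without a gene symbol, which enter no comparison of the report, also carried signal: of 5683 such probes, 1383 and 1402 changed after 3 days of denervation in wild type and knockout, and 1670 and 1529 after 14 days.

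Other divisions of the same arrays into groups of these sizes were fitted the same way, 100 of them for each interaction and for the comparisons of 6 against 6 arrays. Only the real division called as many genes for genotype in control muscle (1 of 100, 374 genes against 300 in the highest other) and day in control muscle (1 of 100, 4685 against 2638). These shares argue against chance as the account of the whole count, not of each call. The 374 genes include 46 in the window around Trim63, so the share does not speak for the 327 called elsewhere by themselves. For the day 14 interaction and that of all 3 factors the share was also 1 of 100, with 267 and 260 genes in the highest other. As many genes were called in 4 of 100 divisions for day by denervation in knockout, where the highest other called 3582 against 2330. For the day 3 interaction 9 of 100 did and the highest called 502. For day by denervation in wild type 10 of 100 did and the highest called 5194. The counts of all 3 factors and of day by denervation in knockout also fell without the 2 arrays of most detected probes. For the interactions, labels were exchanged separately within control and within denervated arrays. A division can then turn an interaction into the sum of the day or genotype differences of both treatments. Divisions that call several times the real count can arise in this way, so their share does not measure chance alone. A division that mixes genotypes or days also adds their differences to the spread within groups, which can lower its count. For every interaction chance is therefore left undecided by these shares. With 3 against 3 arrays 10 divisions are too few for a share under 0.05. There the real counts and the highest others were 4244 and 1, 4052 and 1130, 4698 and 1, and 4154 and 1 for denervation on days 3 and 14 in wild type and knockout in turn, and 812 and 296, and 789 and 1, for genotype in denervated muscle on days 3 and 14.

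Genes that differed between the genotypes in control muscle lay more often around Trim63 than elsewhere, 46 of them in a window set after the gene names had been seen. Loss of MuRF1 acting on genes wherever they lie is argued against, as the whole account of these calls, by the neighbours listed before the data were seen, whose odds ratio of a call was 12.8 (5.14 to 29.5). Of 14 second probes of called window genes 12 had the same sign (57.2% to 98.2%), against 122 of 169 elsewhere. Because same signs were also common elsewhere, this count cannot decide on sequence variants under the probes. Of the 14, 7 passed by themselves in the same direction, against 48 of 169 elsewhere. For these 7, variants under the probe used are argued against as the account of the sign, not of the size. The window genes with a second probe that differed at least 2-fold were Eya3, E2f2, Rbp7, Hyi and Clstn1. Their second probes stood at -0.02, -0.06, -0.17, 0.28 and 0.08 log2. Variants stay open for the size of these changes and for the 7 genes whose second probe did not pass in the same direction. They stay open too for 32 called genes with 1 probe. A difference of the chromosome segment carried along with the targeted gene is a candidate explanation. Of the called window genes 73.9% (58.9% to 85.7%) kept their sign in denervated muscle of both days. Of 327 called genes elsewhere 92 (28.1%) did, so most calls outside the window did not keep their sign there on both days. That share is little more than signs drawn at random for each day would give. Whether window genes alter the response to denervation was not tested.

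The calls between genotypes in denervated muscle at day 3 depended on which knockout arrays were kept, judged from 1 knockout sample at a time, assumed to vary like the other groups. With only the array of fewest detected probes kept in that group, 24 genes were called, against 876 and 1228 with either of the 2 others alone. Over all 3 knockout arrays the difference from wild type correlated across genes with the difference of day 14 from day 3 in control muscle (r = 0.429). These comparisons share no arrays, so a difference between arrays that also parts the days may account for a share of the day 3 calls. Taken singly, denervated knockout replicates 1, 2 and 3 gave r = 0.00449, 0.416 and 0.559, replicate 1 being the array of fewest detected probes. Denervated wild type replicates 1, 2 and 3, each set against the others, gave 0.225, -0.0685 and -0.187. At day 14 the genotype difference went the other way along the day difference (r = -0.274), and genes are not independent replicates. An effect of genotype stays open, as untested by these values.

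Synapse genes were lower in denervated knockout muscle at day 14. As a test of dilution of muscle RNA by RNA of other cells, fast-fibre and coupling genes had a median difference of 0.0331 (-0.0881 to 0.147). The synapse list had -0.633 (-0.81 to -0.245). These intervals come from resampling genes, not samples. The values argue against dilution only if genotype left fast-fibre and coupling genes otherwise unchanged. Coupling genes had a higher change in the knockout in the day 14 interaction, so dilution offset by such a change could not be told apart. List medians of other cells were higher there with the preset correlation (macrophage 0.68, with 1 of 19 genes passing, as lower, and endothelial 0.32, 2 of 15 higher). The extracellular matrix, fibroblast, adipocyte and slow-fibre lists passed there too. None of these lists passed with an estimated correlation (adjusted p = 0.447 for macrophage and endothelial markers), so more RNA of such cells stays open. A different number of detected probes is argued against by the list's median of -0.633 with that number as a covariate (adjusted p = 6.7e-07). A response smaller by the same share in all genes could not be told apart from an effect of MuRF1 loss on synapse transcripts. Summed over the list's genes, the day 14 log2 change in knockout was 67% of that in wild type (25.8% to 80.7% by resampling genes). That of the score genes, signed by their day 3 direction, was 84.4% (74% to 96.4% by choice of genes). These ratios of sums weigh large changes most and are not ratios of list medians.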

How the results depend on the processing

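The detected-probe covariate, the 2 omitted arrays and the omission of genes around Trim63 were alternatives chosen after the data had been seen; all others were planned. The block by slide was not run, since no slide is named. Denervation counts in wild type stayed within 1.5 times under every alternative run, and Trim63 stayed lower in knockout under each. Median centring moved the median of all genes by up to 0.1455 log2, and the other alternatives by at most 0.0525. The same replicate number did not mark pairs of samples: 1 of 36 pairs correlated above 0.1 (-0.2877 to 0.3889). Signal over background limits bounds for genes undetected in a group. For every value below the cause was not tested, save that fewer samples were fitted where samples were left out.

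The day 3 interaction gave 80 genes with the authors' values, 248 without background correction, 70 with median centring, 60 without a filter, 71 with the mean of probes, 229 with trend and robust variance, 2229 with array weights, 60 with the replicate block, 10 with the covariate, 17 with only the day's samples and 3 without the 2 arrays. Genotype in denervated muscle at day 3 gave 1304 without background correction, 3017 with weights, 40 with the covariate, 154 with only the day's samples and 24 without the 2 arrays. Genotype in control muscle gave 661, 1492 and 249 without background correction, with weights and with the replicate block, and 197 with only its groups. Array weights gave 2619 for the day 14 interaction, 2245 for genotype in denervated muscle at day 14, 2557 and 4544 for day by denervation in wild type and knockout and 3639 for all 3 factors. The covariate gave 1672 for denervation at day 3 in knockout, 2415 and 1788 for the day 14 interaction and genotype in denervated muscle, 1093 for day by denervation in knockout, 817 for all 3 factors and 224 for day in control muscle. Only the samples of its groups gave 1094 for day by denervation in knockout. Leaving out the 2 arrays gave 1932 for denervation at day 3 in knockout, 220 for day by denervation there and 99 for all 3 factors.

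The day 14 score difference was 0.0402 with day 3 genes chosen under the covariate (permutation p = 0.055, the sign reversed). It was -0.0348 with day 3 genes chosen without the 2 arrays (permutation p = 0.125). The day 14 samples scored were the same in both. Genes called in wild type gave -0.026 and -0.0608 at days 14 and 3. With an estimated correlation 26 list tests passed. Also reversed were oxidative phosphorylation between days in control muscle with median centring (0.019), extracellular matrix and fibroblast lists in the day 3 interaction with the covariate (0.2415 and 0.2978), and macrophage markers by genotype at day 3 with the covariate (0.4028) and without the 2 arrays (0.3391).

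With each replicate left out in turn the counts ranged from 3663 to 3737 and 4095 to 4245 for denervation on days 3 and 14 in wild type, from 3275 to 4281 and 3443 to 3820 in knockout, from 31 to 985 and 708 to 1477 for the interactions at days 3 and 14, from 179 to 2171 and 301 to 687 for genotype in denervated muscle and from 169 to 738 in control muscle. They ranged from 1170 to 1425 and 1425 to 3276 for day by denervation in wild type and knockout, from 1004 to 2699 for all 3 factors, from 3944 to 5092 for day in control muscle and from 128 to 139 for list tests. The scores ranged from -0.1921 to -0.1214 and from -0.2253 to -0.1531 at days 14 and 3. Where a group kept 2 samples, or 1 without the 2 arrays, the spread was pooled over all groups and a lone sample assumed to vary like the others.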

Other observations

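After denervation some lists moved little or in both directions, and none of the 6 named in this paragraph passed in any of the 4 denervation comparisons. Schwann cell markers passed elsewhere, by genotype in control muscle (1 of 13 higher, median 0.17, adjusted p = 0.0344). That call ended in 10 of 25 alternatives: the authors' values (0.0566), no background correction (0.129), a stricter filter (0.282), an estimated correlation (0.481), genes around Trim63 left out (0.297) and 5 left-out samples. These were day 3 control wild type replicate 2 (0.0937), day 3 control knockout replicates 2 and 3 (0.0719 and 0.0962), day 14 control wild type replicate 3 (0.055) and day 14 control knockout replicate 2 (0.0703). Circadian genes passed by genotype in denervated muscle at day 14 (3 of 13 lower, 4 over the list alone, median -0.22, adjusted p = 0.0444). Of 19 alternatives 9 ended this call: a stricter filter (0.0539), the mean of probes (0.11), the replicate block (0.0543), only the day's samples (0.0738), an estimated correlation (0.447) and 4 left-out samples. These were denervated wild type replicates 2 and 3 (0.0943 and 0.0916) and denervated knockout replicates 2 and 3 (0.11 and 0.0674). Neighbours of Trim63 passed by genotype in day 3 denervated muscle and in control muscle (2 higher and 7 lower of 30, 2 and 8 over the list alone, median -0.11, adjusted p = 0.0262). The call in control muscle ended with a stricter filter (0.0905), with an estimated correlation (0.19) and without day 3 control knockout replicates 1 and 3 (0.0529 and 0.0617). Of 22 ATF4 and amino acid stress genes 8 rose and 2 fell at day 3 in wild type (9 and 3 adjusted over the list alone; median 0.10, adjusted p = 0.168), with the amino acid transporter Slc7a5 up 4.43-fold. Of 7 polyamine genes 3 rose and 2 fell (median -0.14, adjusted p = 0.605), with Smox, which oxidizes spermine, down 3.13-fold. Schwann cell and myelin markers rose in 4 and fell in 6 of 13 (median -0.10, adjusted p = 0.428), with the myelin protein Mbp down 5.78-fold. In day 3 knockout muscle their median was 0.22 while the test pointed lower, the mean being -0.11. Circadian clock genes rose in 4 and fell in 3 of 13 (4 and 4 over the list alone; median -0.08, adjusted p = 0.771), red blood cell markers fell in 1 of 7 (median -0.05, adjusted p = 0.508), and neighbours of Trim63 rose in 9 and fell in 4 of 30 (10 and 4 over the list alone; median 0.22, adjusted p = 0.0585).

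Fibroblast markers fell in 3 and rose in 1 of 12 at day 3 in wild type (5 and 1 over the list alone; median -0.23, adjusted p = 0.17). The 2 interactions of genotype with denervation shared 4 genes higher and 8 lower in both, against 3.39 and 3.96 for independent lists, and 19 with opposite signs, against 8.16. Genotype in control muscle gave 58 genes at day 3 and 621 at day 14, with 18 shared in direction.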
